A study of Drosophila melanogaster with 9 samples.

How the data were processed

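RNA from whole dechorionated Drosophila melanogaster embryos was hybridised to Affymetrix Drosophila Genome 2.0 arrays, 1 biotin-labelled total RNA sample per array. The labels give 3 groups of 3 arrays. These are embryos homozygous for a P-element allele of cabut (cbt), w1118 embryos as control, and embryos in which the epidermal driver 69B-Gal4 directs a UAS-Cbt transgene. All embryos were staged 10 to 13. About 1000 embryos went into each mutant and each overexpression sample. The number for w1118 is not given in the sources used here. The mutants were sorted as the embryos without GFP from a stock whose balancer carries twi-eGFP. No driver-only control was analysed here.

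The deposited values are 1 log2 expression level per probe set and array. RMA, affy and limma are named as tools, without versions, per the submitters' processing notes. The chip definition file and any filter are not given in the sources used here. The log2 scale was checked on the hybridisation controls, whose level rose by 0.863 to 1.26 units per doubling of their nominal concentration. This slope was 1.20 and 1.26 on w1118 replicates 1 and 3 but 0.917 on w1118 replicate 2. It was 1.00 to 1.10 on the mutant arrays and 0.863 to 0.922 on those labelled overexpression, so the arrays did not share exactly 1 scale. Array medians lay between 0.85 and 1.06, and upper quartiles between 3.14 (overexpression replicate 1) and 4.03 (w1118 replicate 1). The table has 18952 probe sets, of which 183 Affymetrix controls were kept out of all tests, leaving 18769. No detection flags were used. The highest Tag control probe set of each array, which has no fly target, served as the background level (0.58 to 1.20). A group whose mean lay at or below its background level has only a bound, so the brighter group is then given as at least N-fold higher. Between 43.8% and 62.0% of probe sets exceeded that level on an array. The number of arrays, 3 per group, limits the precision. Nothing in the labels says that the 3 RNA samples of a group came from separate collections, so p-values measure only the spread between these samples, which may be technical.

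Probe sets were named through the platform annotation, which gives 1 gene symbol for 13647 probe sets, several for 402 and none for 4720. Symbols were updated by gene ID for 13544 probe sets with the RefSeq table of assembly Release 6 plus ISO1 MT. The sources name no genome build, so no coordinates are printed. The 13647 probe sets stand for 11982 genes.

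Groups were compared with limma 3.58.1 in R 4.3.3. One linear model with a term per group was fitted to all 9 arrays, with moderated tests, and p-values were adjusted by Benjamini-Hochberg over the 18769 probe sets at a threshold of 0.05. A moderated F test asked for any difference among the 3 groups. The 33 gene lists were fixed before the data were examined and cover dorsal closure pathways, embryonic tissues, stage, growth and stress. The 32 lists with at least 5 measured genes were tested with camera (preset correlation 0.01, brightest probe set per gene), and again with the correlation estimated from the data. The histone list was too small. Counts of list members are also given adjusted over the list alone. The reference values for the 2 comparisons that share the w1118 arrays came from 100 simulations of unchanged groups with the fitted spread. These gave the 3 groups the same spread and drew probe sets independently.

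The genes to be named were set by a rule fixed in advance. They are cbt and white, then per comparison the 10 largest rises and 10 largest falls among probe sets with an adjusted p under 0.05, no overlap between the arrays of either group, 1 symbol, and a level in the higher group above the median of all probe sets. Where fewer than 10 passed, those with the smallest p were added as not passing. Up to 4 called members per list, the 2 members with the smallest p of the JNK, Dpp and amnioserosa lists, and 5 genes per shared direction were added. No probe set of white was named by the annotation, so white was not analysed here. Of a gene with several probe sets, the one with the larger change is given, and differing probe sets are mentioned.

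The procedure was tested on simulated data with the real means and fitted spreads, with 18769 probe sets and 50 changed ones per size. In the simulated mutant versus w1118 comparison, 14% of changes of 1 log2 unit, 64% of 2 units, 92% of 4 units and 94% of 6 units were recovered, with 6 false calls. The shares were 12%, 62%, 94% and 96% for overexpression label versus w1118 and 12%, 64%, 96% and 100% for overexpression label versus mutant. In a simulated list shift of 1 unit, the shifted list was called and 0 other lists were. The simulated genes varied independently, so this does not test the lists under correlation between genes. In the data that correlation was estimated at 0.59 for the cytoskeleton and adhesion list.

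The alternatives set in advance were medians set equal, cyclic loess, 2 filters on dim probe sets, trended and robust eBayes, array weights, a fit of only the 2 groups compared, a block on the replicate number, 1 probe set per gene, list tests with other settings, and leaving out each array. Chosen after seeing the data were w1118 replicate 2 as the only control, a term for the 2 arrays with the lowest poly-A spike-in controls, and removal of each array's trend on gene length, with its baseline. Gene length is the genomic span in the RefSeq table, which had a value for 99.3% of singly named probe sets. The spike-in term varied only within w1118, so its fold changes against w1118 were those against w1118 replicate 2. Plots were drawn with matplotlib.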

Results

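Cabut (cbt, also dTIEG) encodes a Krüppel-like zinc finger transcription factor that embryos need for dorsal closure, when the lateral epidermis is drawn over the amnioserosa. Transcript levels were measured on 9 arrays, with 3 each from cbt mutant embryos, from w1118 control embryos and from embryos labelled as overexpressing Cbt in the epidermis. The embryos were at stages 10 to 13. The comparisons ask which transcripts change when cbt is lost, which change when it is supplied in excess, and whether the same genes respond to both. In the moderated F test of limma, 73 of 18769 probe sets differed among the 3 groups, against 37 without mutant replicate 3, 6978 without w1118 replicate 2, and 34, 33 and 27 without overexpression replicates 1, 2 and 3.

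The targeted gene was examined first. The single cbt probe set stood at a log2 level of 6.73 ± 1.02 (SD, n = 3) in w1118, 4.26 ± 0.42 (SD, n = 3) in the mutant and 3.36 ± 0.33 (SD, n = 3) in the arrays labelled overexpression. In the mutant it was lower than in w1118 by a log2 fold change of -2.46 (SE 0.48), which did not pass the threshold (limma adjusted p = 0.19). All 3 mutant arrays lay below all 3 control arrays. In the arrays labelled overexpression cbt fell by 3.37 (SE 0.48, adjusted p = 0.0436), against the direction of the label. The difference between the arrays labelled overexpression and the mutant was -0.91 (SE 0.48, adjusted p = 0.337). Which part of the transcript the probe set covers, and whether the transgene holds it, was not analysed here. Directions in that group are therefore given for the arrays labelled overexpression. The call in that group was lost without any 1 of mutant replicates 1, 2 and 3, w1118 replicate 1, or overexpression replicates 1, 2 and 3, at adjusted p of 0.074, 0.0766, 0.100, 0.0781, 0.179, 0.154 and 0.157. It was also lost with only the 2 groups fitted (0.165). With w1118 replicate 2 as the only control the fold change was -2.70. A term for the poly-A spike-in split gave the same value, since it varies only within w1118 and leaves replicate 2 as the reference. In the mutant, the fold change without w1118 replicate 2 was -2.80 and passed (adjusted p = 0.0049). That setting leaves w1118 replicates 1 and 3 as the only controls. Their spike-in controls differed from those of all other arrays (below), so genotype cannot be separated there from that difference. Among the neighbouring genes within 100 kb, including ush, whose span contains cbt, no other probe set passed in any of the 3 comparisons.

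**Figure D1:**
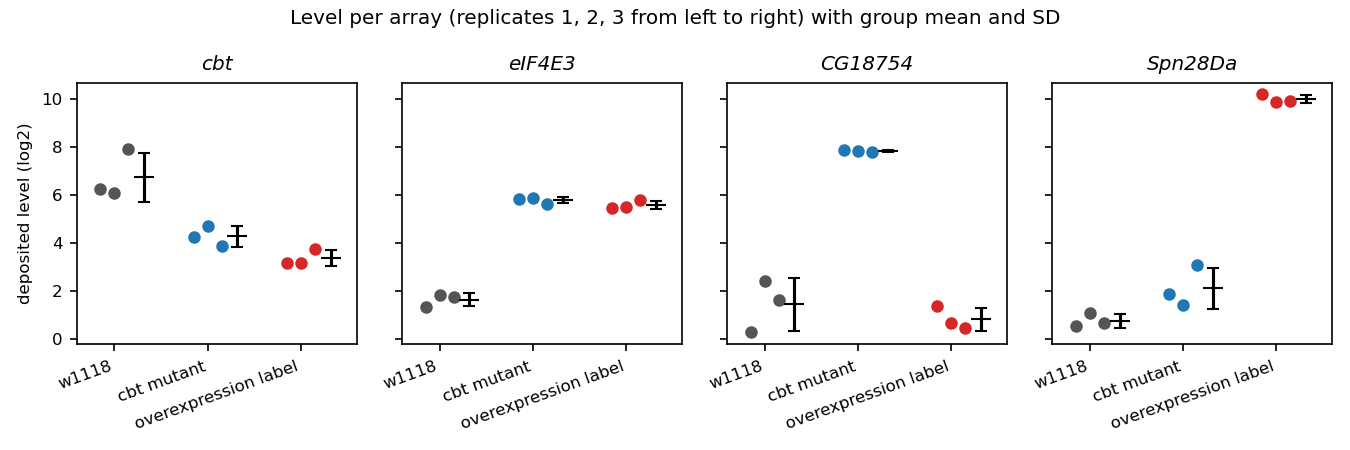
Deposited log2 level (y axis) of 4 genes on each array, with 1 point per replicate and the group mean with its SD as the bar beside it, for w1118, the cbt mutant and the arrays labelled overexpression (x axis). cbt was lowest in the arrays labelled overexpression (mean 3.36), eIF4E3 was at 5.77 in the mutant and 5.58 in the arrays labelled overexpression, CG18754 was at 7.82 in the mutant, and Spn28Da was at 9.99 in the arrays labelled overexpression.

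The arrays of the w1118 group did not form a single cluster. w1118 replicates 1 and 3 correlated at r = 0.987 across probe sets, whereas replicate 2 correlated with these at 0.890 to 0.894 and with the arrays labelled overexpression at 0.968 to 0.981. Replicate 2 correlated with the mutant arrays at 0.957 to 0.970. For replicates 1 and 3 the values were 0.922 to 0.955 with the mutant and 0.842 to 0.886 with the arrays labelled overexpression. The first principal component held 68.2% of the variance, with scores of 95.7 and 100.6 for w1118 replicates 1 and 3 and of -40.5 for replicate 2. The mean of the poly-A spike-in controls was 1.91 and 2.42 on w1118 replicates 1 and 3 and between 3.09 and 4.03 on the other 7 arrays. Differences between arrays also followed gene length. Values on length are for the 6077 probe sets with a gene length and a mean log2 level above 2. Replicate 2 minus the mean of replicates 1 and 3 had a median of 1.18 for genes of at most 1 kb and -1.40 for genes over 16 kb (Spearman's rho -0.46). The same correlation was -0.58 for mutant minus w1118, -0.40 for overexpression label minus w1118 and -0.13 for overexpression label minus mutant. These are correlations across genes, which are not independent replicates.

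**Figure D2:**
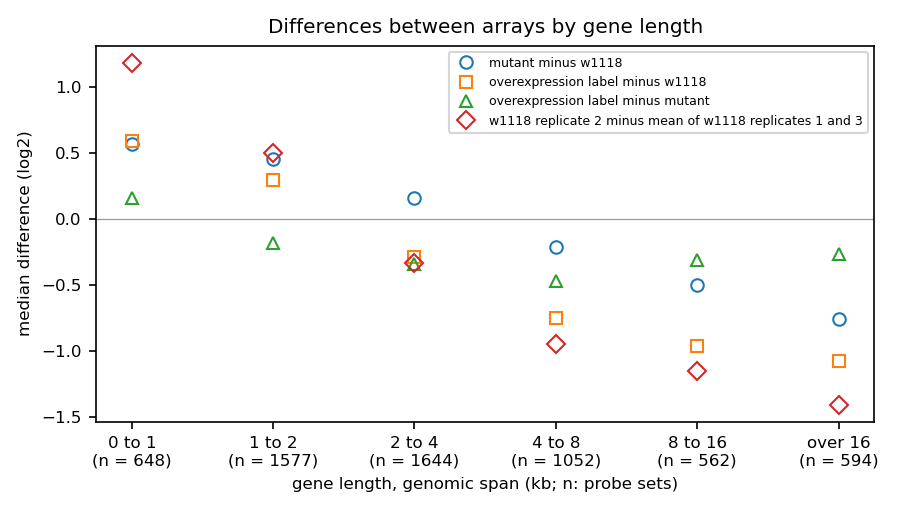
Median log2 difference (y axis) of probe sets in 6 bins of gene length (x axis, genomic span in kb, with the number of probe sets), for the 3 group comparisons and for w1118 replicate 2 against the mean of w1118 replicates 1 and 3. The last of these runs from 1.18 in the shortest bin to -1.40 in the longest, and mutant minus w1118 from 0.56 to -0.75. Only probe sets with a mean log2 level above 2 are included.

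The first comparison asks which transcripts differ between the arrays labelled mutant and w1118. Whether the former hold only homozygous embryos is open, since control probe sets of unknown target stood higher there than in w1118 (below). In the mutant, 18 probe sets were higher and 7 lower than in w1118, 25 in all, for 21 named genes. The arrays of the groups did not overlap for 1838 probe sets (9.79%), where chance gives 10%. The largest rise among called genes was in CG18754, from 1.42 ± 1.08 to 7.82 ± 0.05 (SD, n = 3 each, adjusted p = 0.004). eIF4E3, a member of the cap-binding translation factor family, rose by 4.15 (SE 0.17, adjusted p = 8.49e-05), from 1.62 ± 0.28 to 5.77 ± 0.13. CG32299 was at background in w1118 and at least 10.2-fold higher in the mutant (adjusted p = 8.49e-05), and CG43090 at least 5.93-fold higher (adjusted p = 0.0026). CG31792, the zinc transporter gene Zip102B and CG8745 rose by 2.77, 2.59 and 2.48. SPE, the protease that processes the Toll ligand Spätzle, rose by 2.28, the xanthine dehydrogenase gene ry by 1.96, and the odorant receptor gene Or71a by 1.92.

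Of the 25 called probe sets, 7 fell in the mutant, but the balance turned with array weights (2422 higher and 2907 lower) and without w1118 replicate 2 (1709 and 2278). Rcd7 fell by 3.93 (SE 0.44, adjusted p = 0.0233), Dred by 3.86 (SE 0.23, adjusted p = 0.000836), MESR6 by 3.60 and CG18088 by 3.49. CG4849 fell by 2.24 on one probe set, while its other probe set was higher by 0.87 and did not pass. The next genes in order of p, which did not pass, had values of -4.80 for the RNA-binding protein gene Hrb87F (adjusted p = 0.062), -1.79 for CG31637, -1.53 for smash (-1.09 on its other probe set), -1.92 for the microtubule-associated protein gene Map205 and -1.70 for CG1631. Of the called genes that the rule named, eIF4E3 and CG32299 passed under each of the 21 alternatives run for single genes.

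Among the lists for dorsal closure, 0 of 22 JNK pathway genes, 0 of 24 Dpp pathway genes, 0 of 26 cytoskeleton and adhesion genes and 0 of 15 amnioserosa genes passed over all probe sets. Adjusted over the list alone, 3 Dpp pathway genes and 1 amnioserosa gene fell, and 0 genes of the JNK pathway and the cytoskeleton and adhesion lists passed. As sets, all 4 shifted down with the preset correlation, with medians of -0.67 for the JNK pathway (camera adjusted p = 0.000216), -0.50 for the Dpp pathway (adjusted p = 0.000775), -0.79 for cytoskeleton and adhesion (adjusted p = 4.26e-07) and -0.38 for amnioserosa (adjusted p = 0.022). With an estimated correlation none of these calls held (adjusted p = 0.52 for each). Without w1118 replicate 2, 12 JNK pathway, 13 Dpp pathway, 17 cytoskeleton and adhesion and 7 amnioserosa genes fell over all probe sets. In the same setting 2, 2, 0 and 1 rose, beside 3987 of 18769 probe sets called in all. There the 4 lists were again called down with the preset correlation but not with an estimated one. The controls left there are w1118 replicates 1 and 3, so genotype cannot be separated from what sets them apart from the other arrays. Against w1118 replicate 2 alone none of the 4 was called, and cytoskeleton and adhesion (adjusted p = 0.329) and the Dpp pathway (adjusted p = 0.881) pointed up. The members with the smallest p were raw at -1.05 and the kinase gene Mkk4 at -0.98 in the JNK list, Actbeta, an activin-like ligand, at -4.29 (SE 0.74, adjusted p = 0.132) and tup at -1.08 in the Dpp list, and tup and the GATA factor gene srp (-1.21) in the amnioserosa list.

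The same downward shift was seen in lists of several tissues. Lists shifted down included neurons (median -0.72), trachea (-0.87), muscle (-0.60), glia (-0.52), neuroblasts (-0.70), septate junctions (-0.37), epidermal barrier enzymes (-0.37) and extracellular matrix (-0.51). The lists for early segmentation (-0.51), Wingless and Hedgehog signalling (-0.30), EGFR signalling (-0.31), the Hippo pathway (-0.37), ecdysone (-0.45) and Krüppel-like and Sp factors (-0.30) did too. Cell cycle and replication genes (median 0.37) and ribosomal protein genes (0.15) shifted up. These made 20 of 32 lists with the preset correlation, and 0 with an estimated correlation (smallest adjusted p = 0.52). Beside these shifts stands the split of the controls, since the muscle list had medians of 1.33 and 1.53 on w1118 replicates 1 and 3, -0.91 on w1118 replicate 2 and between -0.09 and 0.10 on the mutant arrays. Against w1118 replicate 2 alone, 13 of the 20 lists pointed the other way, and muscle, epidermal barrier enzymes and extracellular matrix were called up, as were cell cycle genes. Without w1118 replicate 2, the calls of cell cycle genes (adjusted p = 0.538), Wingless and Hedgehog signalling (0.0874) and Krüppel-like and Sp factors (0.135) were lost. Their medians in that setting were 0.36, -0.43 and -0.52, so the lost calls do not show that these shifts rested on that array. With the gene length trend removed, 6 lists were called, among them the JNK pathway and cytoskeleton and adhesion, both down. Without w1118 replicate 1 and without w1118 replicate 3, 13 and 12 lists were called.

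The number of changed probe sets in the mutant rested on single arrays. It was 15 without mutant replicate 3, 3987 without w1118 replicate 2, 12 without w1118 replicate 3, and 14, 13 and 12 without overexpression replicates 1, 2 and 3, which entered only through the shared spread. With only the mutant and w1118 arrays fitted it was 3, with w1118 replicate 2 as the only control 38, with a term for the poly-A spike-in split 111, and with array weights 5329.

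**Figure D3:**
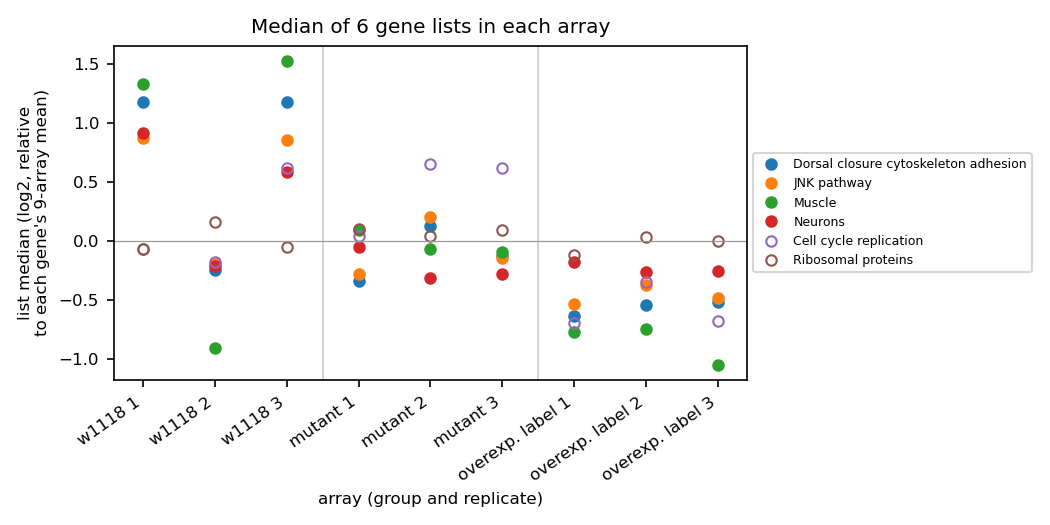
Median log2 level of 6 gene lists on each array (y axis, each gene relative to its mean over the 9 arrays), with the arrays by group and replicate on the x axis. The muscle list stands at 1.33 and 1.53 on w1118 replicates 1 and 3 and at -0.91 on w1118 replicate 2, and the cell cycle list lies between -0.70 and -0.35 on the arrays labelled overexpression.

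The second comparison asks which transcripts change with the UAS-Cbt transgene. In the arrays labelled overexpression, 45 probe sets were higher and 25 lower than in w1118, 70 in all, for 56 named genes. The arrays did not overlap for 5448 of the 18769 probe sets, where chance gives 10%. With cyclic loess, 51 were higher and 16 lower. The largest rise among called genes was in Spn28Da, a serpin gene, from 0.74 ± 0.29 to 9.99 ± 0.17 (SD, n = 3 each, adjusted p = 4.89e-05). RFeSP, a Rieske iron-sulfur subunit of mitochondrial complex III, was at background in w1118 on one probe set and at least 27.1-fold higher (adjusted p = 1.77e-06), while its other probe set was higher by 1.69 and did not pass. CG34188 was at least 16.9-fold higher (adjusted p = 1.77e-06), and its other probe set stayed at background in every group. eIF4E3 rose by 3.96 (SE 0.17, adjusted p = 4.89e-05), as it had in the mutant. The cytochrome P450 gene Cyp6a16 rose by 3.76, CG11170 by 3.49 and the odorant-binding protein gene Obp99b by 3.16. EndoU rose by 3.46 on one probe set, and its other probe set, at -1.04, did not pass. The gene fit was at least 8.67-fold higher, CG33093 rose by 2.92, and PH4alphaSG2, a prolyl hydroxylase of the salivary gland, rose by 2.71.

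Among called genes with a single name, the largest falls after cbt itself were in MESR6 (-3.14), Mst85C (-3.02) and Arc1 (-2.70), a capsid-forming relative of mammalian Arc whose other probe set, at -0.55, did not pass. CG4849 was at background in the arrays labelled overexpression and at least 4.36-fold higher in w1118 on one probe set (adjusted p = 0.0016), while its other probe set stood at 5.28 in w1118 and 5.45 in the arrays labelled overexpression and did not pass. CG32572 was at least 3.96-fold higher in w1118. Fpps, the farnesyl pyrophosphate synthase gene of the isoprenoid pathway, fell by 2.14. CG13217, the glycosyltransferase gene Ugt50B3 and CG7900 fell by 2.02, 1.99 and 1.87. Of the called genes that the rule named, Spn28Da, RFeSP, CG34188, eIF4E3 and CG4849 passed under each of these 21 alternatives.

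Over all probe sets, no member of the JNK, Dpp, cytoskeleton and adhesion, or amnioserosa lists passed. Adjusted over the list alone, 17 of 26 cytoskeleton and adhesion genes fell, and 15 of 22 JNK pathway genes fell and 1 rose. Of 24 Dpp pathway genes 12 fell and 3 rose, and of 15 amnioserosa genes 7 fell and 1 rose. This was not particular to these lists. In the same way 10 of 22 Notch signalling, 8 of 13 EGFR signalling (1 rose) and 8 of 21 neuroblast genes fell, but 0 of 17 trachea genes did. Over all 18769 probe sets, 5981 had an unadjusted limma p under 0.05. In the JNK list the kinase gene msn was at -1.54 and Tab2 at -1.32. In the Dpp list tld, a protease that releases Dpp, was at -1.85 (adjusted p = 0.0536) and the co-Smad gene Med at 0.63. In the amnioserosa list Ance was at 1.38 (adjusted p = 0.0536) and the receptor gene Tl at -1.72, with its other probe set at 0.14. Chosen after their values were seen, the junction genes cno, Rok and crb of the cytoskeleton list stood at -2.49, -2.03 and -2.56. As sets, 18 lists were shifted down and 0 up with the preset correlation. Medians were -1.31 for cytoskeleton and adhesion (camera adjusted p = 3.3e-07), -1.19 for the JNK pathway (adjusted p = 0.000266), -0.78 for the Dpp pathway and -1.08 for amnioserosa. None of the 18 held with an estimated correlation (smallest adjusted p = 0.496). Without w1118 replicate 2, 16 JNK pathway, 16 Dpp pathway, 22 cytoskeleton and adhesion and 10 amnioserosa genes fell over all probe sets. In the same setting 3, 3, 0 and 3 rose, beside 7625 of 18769 probe sets called in all. The controls were again only w1118 replicates 1 and 3, with the same limit.

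The other lists shifted down were muscle (median -1.90), heat shock (-1.61), trachea (-1.52), neuroblasts (-1.21), septate junctions (-1.21), EGFR signalling (-0.97), early segmentation (-0.96), the Hippo pathway (-0.89), ecdysone (-0.88), Notch signalling (-0.86), epidermal barrier enzymes (-0.79), glia (-0.66), neurons (-0.63) and the cell cycle (-0.55). On w1118 replicate 2 the cytoskeleton and adhesion list had a median of -0.25 and the JNK list of -0.19, against 1.18 and 0.85 on w1118 replicate 3. Against w1118 replicate 2 alone, 4 lists were still called down, namely the JNK pathway (adjusted p = 0.0034), cytoskeleton and adhesion (adjusted p = 0.0445), the cell cycle and heat shock (adjusted p = 0.000661 for both), while muscle, glia and epidermal barrier enzymes pointed up without being called. With the gene length trend removed, 8 lists were called.

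The count of 70 (45 higher and 25 lower) became 30 without mutant replicate 3, 45, 7625 and 27 without w1118 replicates 1, 2 and 3, and 22, 23 and 11 without overexpression replicates 1, 2 and 3. With only the 2 groups fitted it was 18, with w1118 replicate 2 as the only control 38, with the spike-in term 22, and with array weights 8846. Without w1118 replicate 2, 3680 were higher and 3945 lower.

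The third comparison sets the arrays labelled overexpression directly against the mutant and uses the w1118 arrays only for the spread. Of 48 called probe sets, 22 were higher and 26 lower in the arrays labelled overexpression, for 40 named genes. The arrays did not overlap for 7243 probe sets (38.6%), where chance gives 10%. Spn28Da was higher by 7.89 (adjusted p = 0.000137), and on one probe set each RFeSP at least 27.0-fold (adjusted p = 2.47e-06), CG34188 at least 16.8-fold (adjusted p = 2.47e-06) and EndoU at least 14.9-fold. Their other probe sets, at 1.21 (7.80 in the mutant and 9.01 in the arrays labelled overexpression), -0.01 and -0.30, did not pass. The gene fit was at least 8.63-fold higher. The receptor tyrosine kinase gene sev was higher by 2.56, Dred by 2.55, the growth-blocking peptide gene Gbp1 by 2.43, ninaD, a scavenger receptor for carotenoids, by 2.42, and CG13640 by 2.41. In the other direction CG18754 was at least 107-fold higher in the mutant, CG32299 at least 7.83-fold, CG31792 at least 7.62-fold, ApepP at least 4.83-fold, CG43090 at least 4.56-fold and Ance-3 at least 2.74-fold. The other probe set of Ance-3 stood at 0.33, 0.29 and 0.45 in w1118, the mutant and the arrays labelled overexpression. CG3226 (-3.84), Mst85C (-3.01), CG13599 (-2.91) and PCID2 (-2.26) were lower in the arrays labelled overexpression.

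Of the lists, cell cycle and replication genes had the smallest camera p between the mutant and the arrays labelled overexpression. Of 31 measured, 28 had negative values, 18 fell when adjusted over the list alone and 0 passed over all probe sets (median -0.97, camera adjusted p = 4.39e-09, and 0.948 with an estimated correlation). Chosen after their values were seen, the replication gene PCNA stood at -2.29, the mitotic checkpoint gene Bub3 at -1.81 and the cyclin gene CycB at -1.45. Notch signalling (median -0.65, adjusted p = 0.0076, 6 of 22 fell adjusted over the list alone) and cytoskeleton and adhesion (median -0.53, adjusted p = 0.0344, 0 of 26) were the other lists called. With an estimated correlation neither of these held (adjusted p = 0.948 for both). In the JNK, Dpp and amnioserosa lists the members with the smallest p did not pass, with values of -1.22 for Tab2, 1.13 for jub, -1.88 for tld, 4.63 for Actbeta, -1.96 for Egfr and -1.67 for Doc1. Without mutant replicate 1 and without w1118 replicate 2, 6 and 5 lists were called.

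Fitted on the mutant and overexpression arrays alone, the same comparison called 2595 probe sets (1179 higher and 1416 lower), which included all 48. It called 2999 without w1118 replicate 2, 90 without w1118 replicate 3, 24 and 25 without mutant replicates 2 and 3, and 28 and 26 without overexpression replicates 1 and 3. With array weights it called 3802. Setting the array medians equal moved the median of all probe sets in this comparison from 0.08 to -0.04. Of 20 called genes that the rule named, 12 passed under each of these 21 alternatives, among them Spn28Da, RFeSP, CG34188, EndoU, fit, Dred, CG18754 and CG32299.

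The last comparison asks whether the mutant and the overexpression change the same genes. No driver-only control was analysed. A probe set that moves alike in both groups therefore cannot be told apart from a difference between w1118 and the other stocks unrelated to cbt. Against w1118, 8 probe sets were called in both, all in the same direction, and 0 in opposite directions. Higher in both were eIF4E3, CG6028 (1.85 in the mutant and 2.16 in the arrays labelled overexpression), SPE (2.28 and 1.64), Or71a (1.92 and 1.61) and mth, a G protein-coupled receptor gene that was at least 2.45-fold and 2.51-fold higher. Lower in both were MESR6 (-3.60 and -3.14), CG4849 on one probe set (its other was at 0.87 and 0.17, not passing) and a probe set without a single gene name. Independent lists would share 0.0525 probe sets in the same direction and 0.0408 in opposite directions, but these values leave out that the comparisons share their w1118 arrays. Simulated unchanged groups against the same controls shared 0. With no effects hardly any probe set can be called in either comparison, so that 0 was nearly fixed in advance. Neither value can show whether 8 exceeds what shared controls give. Without w1118 replicate 2 the counts in the same and in opposite directions were 3656 and 7. They summed to 4, 5 and 4 without mutant replicates 1, 2 and 3, to 3 without w1118 replicate 3, and to 2 without any 1 overexpression replicate.

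Across probe sets the 2 fold changes correlated at r = 0.634, where simulated unchanged groups sharing the same controls gave 0.498. The covariance was 0.266 against a simulated 0.0552, a difference of 0.211. The simulation gave all 3 groups the same spread and drew probe sets independently. In the data r between arrays was as low as 0.890 within w1118, against 0.969 or more within the other groups. A wider spread of the shared controls raises both values, so the simulated ones are not a chance level here. The 3 control arrays could not be split into parts of 2 arrays each, and part or all of the difference may come from the shared controls. The correlation was 0.448, 0.849 and 0.376 without w1118 replicates 1, 2 and 3, and 0.165 with w1118 replicate 2 as the only control.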

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

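The tests in this part were chosen after the values they bear on had been seen, except the counts over other splits of the samples, which were set before. No group has the 4 arrays needed to test for a single outlying sample.

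A signal in data outside the comparisons came from the control probe sets. Of 100 control probe sets with names of the AFFX-Dm family, 2 exceeded the highest w1118 array by more than 1 log2 unit on every mutant array. AFFX-Dm-U57609-2_s_at stood at 5.46 ± 0.63 in the mutant, 0.94 ± 0.31 in w1118 and 1.11 ± 0.04 in the arrays labelled overexpression (SD, n = 3 each), a difference of 4.52 between mutant and w1118. AFFX-Dm-U43284-1_s_at stood at 3.22 ± 1.14 against 0.70 ± 0.23, a difference of 2.52. A higher background on the mutant arrays is argued against by the other 98 sets, whose median difference was 0.0364 and whose highest was 0.30. A marker sequence of the mutant stock is a candidate source of the largest difference of 4.52, but the targets of these probe sets are not in the tables used here, so this stays open. If the target were the GFP marker of the balancer, the arrays labelled mutant could hold embryos that carry the balancer and are not homozygous, and every value given for the mutant, including the cbt level of 4.26, would then describe such embryos or a mixture.

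The second pattern is w1118 replicate 2, which resembled the mutant arrays and the arrays labelled overexpression more than its own group. An array labelled overexpression under the w1118 label is argued against by the 8 probe sets called and more than 3 units higher in that label than in the mutant, in a fit without w1118, where replicate 2 lay at a median of 0.0044 of the way from mutant to overexpression label (quartiles -0.02 and 0.38). Over the 51 probe sets higher in the mutant, replicate 2 lay at 0.23 of the way from overexpression label to mutant (quartiles 0.09 and 0.46), which argues against an array of the mutant but leaves it close to the overexpression label and far from w1118 replicates 1 and 3, at 0.996 and 1.15. RNA quality or labelling that acts along gene length is argued against as the whole cause, because with that trend removed replicate 2 still correlated at 0.965 or more with the arrays labelled overexpression and at most at 0.887 with w1118 replicates 1 and 3; length held 14.4% of the variance of the difference. Embryos of an earlier stage, or with fewer differentiated cells, may contribute but were not singled out. The muscle list was at a median of -2.43 on replicate 2 relative to the mean of replicates 1 and 3. Of 10000 lists matched on gene length and level, 0 were as low, and the same held for septate junctions and cuticle proteins. Epidermal barrier enzymes and extracellular matrix (both at the 0.01 percentile) and trachea (0.64 percentile) were low too. These low lists of differentiated tissues go with that explanation. However, Notch signalling was as extreme (-1.16 against a matched 0.46), neuroblasts were low (1.81 percentile), and early segmentation was not raised (-0.68, at the 26.3 percentile). Other control probe sets split the controls beside the poly-A spike-ins. The 3' minus 5' difference of eIF4a was 3.24 and 3.67 on w1118 replicates 1 and 3, and 2.53 to 2.92 on the other 7 arrays. The hybridisation control bioB stood at 4.64 and 3.86 against 5.01 to 6.91. The 3' minus 5' difference of actin, at 4.03 and 4.55 against 4.13 to 4.82, did not split them. RNA quality or labelling acting otherwise than along gene length stays open, as does a separate handling of these 2 arrays. Neither can be separated from their other differences.

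The third pattern is the low cbt level in the arrays labelled overexpression. The shift along gene length is argued against as the whole cause, since cbt was at -3.25 (adjusted p = 0.0323) after its removal. A probe set outside the part of cbt that the transgene makes may show only the endogenous transcript, and the value of -0.91 against the mutant cannot decide this without the probe and transgene sequences. For the same reason an exchange of the mutant and overexpression labels stays open, since the highest array labelled mutant lay below the lowest w1118 array by 1.36 (-1.36), which would count against an exchange only if the probe set reports the transgene. The control probe set AFFX-Dm-K01486-1_at, singled out after its values were seen, stood at 0.67, 1.10 and 1.10 on the arrays labelled overexpression and at 0.20 to 0.45 on the others, the first 2 of these values being below the highest Tag control of their arrays. If its target, which is not in the tables used here, were the Gal4 driver, a signal there would speak for the overexpression label and against an exchange, but values this near background decide neither. The control probe set AFFX-Dm-U57609-2_s_at stood at 5.46 in the arrays labelled mutant and 1.11 in those labelled overexpression. If its target were a marker of the mutant stock alone, this would count against an exchange, but that target is not known here either. A lowering of endogenous cbt by the transgene, which the design would allow, was not tested.

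For other splits of the samples, 3 arrays against 3 give 10 splits, too few for a share under 0.05. Mutant versus w1118 called 25 probe sets, and the highest other split called 1588; 3 of the 10 splits reached 25. That highest split puts w1118 replicate 2 with mutant replicates 1 and 3, which points to a structure of the samples other than genotype. Overexpression label versus w1118 called 70 and versus mutant 48, with 0 as the highest other in both, and 1 of the 10 splits, the real one, as large. For the lists the real counts were 20, 18 and 3, the highest others 20, 18 and 14, and 2, 3 and 4 of the 10 splits were as large. Of 100 splits drawn from the 280 possible for the F test, 6 gave 73 or more probe sets, with 1820 as the highest other, so chance could not be excluded. That split joins w1118 replicates 1 and 3 with mutant replicate 2, and w1118 replicate 2 with overexpression replicates 2 and 3.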

How the results depend on the processing

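w1118 replicate 2 as the only control, the spike-in term and the gene length settings were chosen after seeing the data; the other settings were set before. Leaving out 1 array at a time, probe sets changed numbered 12 to 3987 in mutant versus w1118, 11 to 7625 in overexpression label versus w1118, and 24 to 2999 in overexpression label versus mutant, and those differing among the groups 27 to 6978, each highest value being without w1118 replicate 2. The cbt fold change ran from -2.80 to -1.87 in the mutant and from -3.71 to -2.78 in the arrays labelled overexpression, lists from 12 to 20, 18 to 21 and 2 to 6, the correlation from 0.376 to 0.849, and the shared probe sets from 2 to 3663. Array weights, which gave w1118 replicate 2 a weight of 0.119, called 5329, 8846 and 3802 and an F count of 8658, with cbt in the mutant at -3.17. Only the 2 groups compared gave 3, 18 and 2595, with cbt in the overexpression label at -3.37 (adjusted p = 0.165). In each of these the spread is estimated with less or no weight on replicate 2, or with fewer arrays. Without replicate 2 the controls are only the w1118 arrays whose spike-in controls differed from those of all other arrays.

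The replicate numbers did not pair the samples. Deviations of same-numbered arrays correlated at -0.374 to 0.26, and 1 of 9 arrays correlated best with its own number. With the replicate block the counts were 11, 17 and 30, the F count 23 and the shared probe sets 2, and cbt in the overexpression label was at -3.37 (adjusted p = 0.122).

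With w1118 replicate 2 as the only control the counts were 38, 38 and 2595 and the F count 1239, cbt in the overexpression label was at -2.70 (adjusted p = 0.0716), the lists numbered 4, 4 and 8, and the correlation was 0.165. That lone control array is assumed to vary like the other groups. The spike-in batch term gives the same fold changes against w1118 as that setting, with another estimate of the spread, so it is no separate adjustment. With the spike-in batch term the counts were 111, 22 and 2999 and the F count 1707, cbt was at -2.70 (adjusted p = 0.264), the lists numbered 4, 3 and 5, and the correlation was 0.165. With the gene length trend removed, 45 probe sets were called in overexpression label versus w1118, 6 and 8 lists were called in the comparisons against w1118 and 4 probe sets were shared; the cause was not tested beyond the removal itself. Restricted to probe sets with a gene length, overexpression label versus mutant gave 30, and with 1 probe set per gene 28, with fewer probe sets tested. Among probe sets above the median level, 12, 9 and 1 lists were called; the cause was not tested. With camera's estimated correlation 0, 0 and 0 lists were called.

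Equal medians, cyclic loess, the filters on dim probe sets, and trended and robust eBayes kept the 3 counts within 1.5 times (22 to 27, 64 to 102 and 48 to 68). The adjusted p of cbt ranged from 0.0015 to 0.67 in the mutant and from 0.00052 to 0.264 in the overexpression label, over the alternatives other than the filters on dim probe sets and 1 probe set per gene, under which cbt was not recomputed. For the named genes, no fold change reversed. Most had been named because the arrays of the groups compared did not overlap, so a reversal was hardly possible and its absence is no support. Of 996 values under settings other than leaving out an array, 812 kept their side of the threshold, 128 lost and 56 gained a call; of 747 under leaving out an array, 531 kept, 190 lost and 26 gained. Signal over background limits the dim transcripts, since no more than 62.0% of probe sets exceeded the highest Tag control.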

Other observations

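The hypothesis test in this part was chosen after seeing which genes were called. With the deposited values, all 9 arrays and the preset correlation, 10 lists were called in 0 of the 3 comparisons. Medians in the mutant and in the arrays labelled overexpression, both against w1118, were -0.03 and -0.17 for cuticle proteins, -0.29 and -0.48 for hemocytes, -0.05 and 0.01 for fat body and midgut, and -0.07 and -0.30 for the salivary gland. They were -0.08 and -0.34 for the germline, -0.18 and -0.17 for sugar sensing and metabolism, -0.02 and -0.12 for the circadian clock, and 0.19 and 0.26 for cell death. They were -0.0049 and 0.05 for innate immunity and -0.04 and -0.01 for detoxification and oxidative stress. Some of these were called down under other settings. With the gene length trend removed these were cuticle proteins (adjusted p = 0.0333 in the mutant and 0.00675 in the arrays labelled overexpression) and fat body and midgut (0.0317 in the mutant). Without w1118 replicate 2 they were cuticle proteins (0.00624 and 0.00835), hemocytes (0.0139 in the mutant), fat body and midgut (0.0456 in the mutant) and the germline (0.0499 in the arrays labelled overexpression), and none of these held with an estimated correlation (smallest adjusted p = 0.356). In the detoxification list, adjusted over the list alone, 2 genes rose and 1 fell in the mutant. These were Cyp4e2 (1.53), Cyp6g1 (1.60) and cnc (-0.97), named after their values were seen.

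The heat shock list was called down in the arrays labelled overexpression (camera adjusted p = 0.0048, and 0.496 with an estimated correlation), but its level also varied among the controls. Against w1118 the list median was -1.61 in the arrays labelled overexpression, where adjusted over the list alone 3 of 10 genes fell and 1 rose. Chosen after their values were seen, DnaJ-1 stood at -3.72, Hsp27 at -3.02, Hsf at -0.81 and Hsp60A at 1.73. On the w1118 arrays the list median was 0.45, 0.25 and 2.06 for replicates 1, 2 and 3.

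The mutant stock carries its cbt allele on chromosome 2, so sequence carried along with the allele may account for part of the calls in the mutant. If so, called genes would be enriched on that chromosome. They were not, with 4 of 21 called genes (19.0%) against 4628 of 11872 others (39.0%) on chromosome 2 (one-sided Fisher's exact p = 0.986). A share over the whole chromosome cannot detect a short stretch around the allele. Some genes called in the mutant are neighbours. The spans of CG18754 and SPE, both higher, overlap on 3R, and Dred and Rcd7, both lower, lie close together on 3L. Whether such pairs changed through local sequence differences between the stocks was not tested, nor were other differences outside chromosome 2. Most called genes named for the largest rises and falls in the mutant lie on 3L or 3R. The exceptions are CG43090, CG31792, Zip102B and CG18088. Whether this exceeds the share of all genes there was not tested, so the chromosome 2 result says nothing of sequence carried on other chromosomes.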
